A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

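Chromatin from Cnd2-HA cells arrested in mitosis was immunoprecipitated with an anti-HA antibody and sequenced beside its input, 1 library each. Per the submitters' processing notes, the tools were BWA 0.7.12 and MACS2 2.1.0 and the build was ASM294v2. Per the file headers, peaks were called with MACS 2.1.0.20150731 on paired-end fragments of the ChIP library against the input, with a q-value cutoff of 0.05, at most 1 fragment kept per position, a fragment length of 208 bp and a local background from windows of 1000 and 10000 bp. No pooling of libraries is recorded. The header also gives an effective genome size of 1.87e+09, whereas the 3 chromosomes total 12.6 Mb.

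The deposited list holds 668 peaks with values by the authors' peak caller. Pileup is a signal, the fragment coverage at the summit, after the larger library was scaled towards the smaller, per the file headers. Fold enrichment is a ratio of ChIP pileup to the local background from the scaled input, per the file headers. The significance columns are −log10 of the p-value and of the q-value at the summit, as the authors' caller gave them. Widths are in bp. Folds, heights and q-values were used only within this list, to describe, rank and filter peaks, to compare sets of its peaks, and to recover the background at summits. Removal of fragments with the same ends took 34.7% of the ChIP library and 10.4% of the input, and can lower the tallest peaks by an amount that was not measured here.

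The genome size in the header sets the lowest background the caller allows, which comes to 2.88 scaled fragments there and 429 with the length of the chromosomes. The background at each summit was recovered from the pileup and fold with the caller's pseudocount of 1. As a check, the Poisson p recomputed from it differed from the deposited −log10 p by at most 0.0034 over the 581 peaks compared. At 372 summits (55.7%) the background was below 429. With the background held at 429 or above, 604 of the 668 peaks stayed past the weakest p of the list. The median fold of all 668, with those that did not stay, became 1.54. The 64 others had folds up to 1.91.

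Genes came from the RefSeq annotation of ASM294v3, a later release than the authors' build, and the coordinates printed for peaks are the authors'. The match was checked by shifting the annotation: 117 of 171 tRNA genes lay within 100 bp of a summit without a shift, and 1 to 9 did with shifts of 500 to 5000 bp in either direction. No coordinates were converted. The 4 peaks on a separate sequence named MTR were left out of the comparisons.

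A gene was called near a peak when a summit lay inside it or within 500 bp. Each count was set beside 10000 random placements of the peaks, each kept on its chromosome with its width and summit offset, and was called above or below when outside their central 95% range. Protein-coding lists were also set beside 10000 random lists matched on gene length in 5 groups. Median folds were compared with random sets of peaks of the same number. These percentiles describe this peak list and are not p-values. Shares have exact (Clopper-Pearson) 95% intervals and densities exact Poisson ones, and both cover counting error only. Gaps were taken between neighbouring protein-coding genes, and centromeres as the longest stretch of each chromosome without one.

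The 16 gene lists, the comparisons and the rule for named genes were fixed before the data were examined. That rule took the genes at the 20 peaks of highest fold (the gene holding the summit, otherwise the nearest) and, in each list, up to 3 members with the highest fold at a near peak. Neighbours given to place a summit were added afterwards, as were the rDNA peaks and the background by chromosome. Other settings, chosen at the same time, were stricter sets of peaks (fold at or above the median, −log10 q of at least 10), other distances (inside the gene, 1000 bp, and 250 bp for gene ends), overlap of the peak interval by at least 1 bp, circular shifts of all peaks, leaving out centromeres and the last 50 kb, 100 kb at the chromosome ends, pileup in place of fold and a 500 bp window for base composition. Settings chosen after seeing the data were the background held at the genome mean, peaks away from tRNA and 5S rRNA genes, and chromosome densities without centromeres and ends.

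The counting was tested on simulated data. Of 3200 list counts from randomly placed peaks 2.03% were called, as were 3.44% of 1600 position counts and 6.50% of 200 spacings. In 50 simulated sets peaks were planted at 60 tRNA genes and at 100 gene 3′ ends together, and each excess was called in 100% of the sets. These sets had a median of 81.5 tRNA genes near a summit. Such large planted effects do not show how small an excess would be called. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Reads, coverage tracks, an untagged control and expression measurements were not analysed here.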

Results

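Binding of Cnd2, the kleisin subunit that closes the condensin ring, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in fission yeast (Schizosaccharomyces pombe) held in mitosis. Condensin is the protein complex that folds chromosomes into compact mitotic form. The cells carried Cnd2 fused to an HA tag (strain YUK421), were arrested with 5 µg/mL thiamine and had their chromatin fixed at 25 °C (30 min, 0.5% formaldehyde). There were 2 groups of 1 library each, the anti-HA ChIP and its input, so no value has a replicate check and no p-value is given across genes or peaks. The ChIP library held 39685815 fragments, of which 25933013 were kept after duplicates (34.7%) were removed. The input library held 60564558, with 54272630 kept and 10.4% removed. The question was where condensin sits on mitotic chromosomes.

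Cnd2 peaks were found along all 3 chromosomes, and the strongest 10 lay beside the cell wall genes ecm33, gas1 and exg1, the cell separation genes eng1 and adg2, at rds1, at the RNA genes snoU14 and prl53, and in centromeres I and III. The authors' list held 664 peaks on chromosomes I, II and III, which covered 4.70% of 12.6 Mb. The median peak was 523 bp wide (quartiles 322 and 901.5 bp). Its summit had a fold enrichment over the local background, as the authors' peak caller gave it, of 1.72 (quartiles 1.36 and 2.47). Enrichment exceeded 2-fold at 264 peaks, 5-fold at 32 and 10-fold at 9, with a highest value of 24.4.

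**Figure D1:**
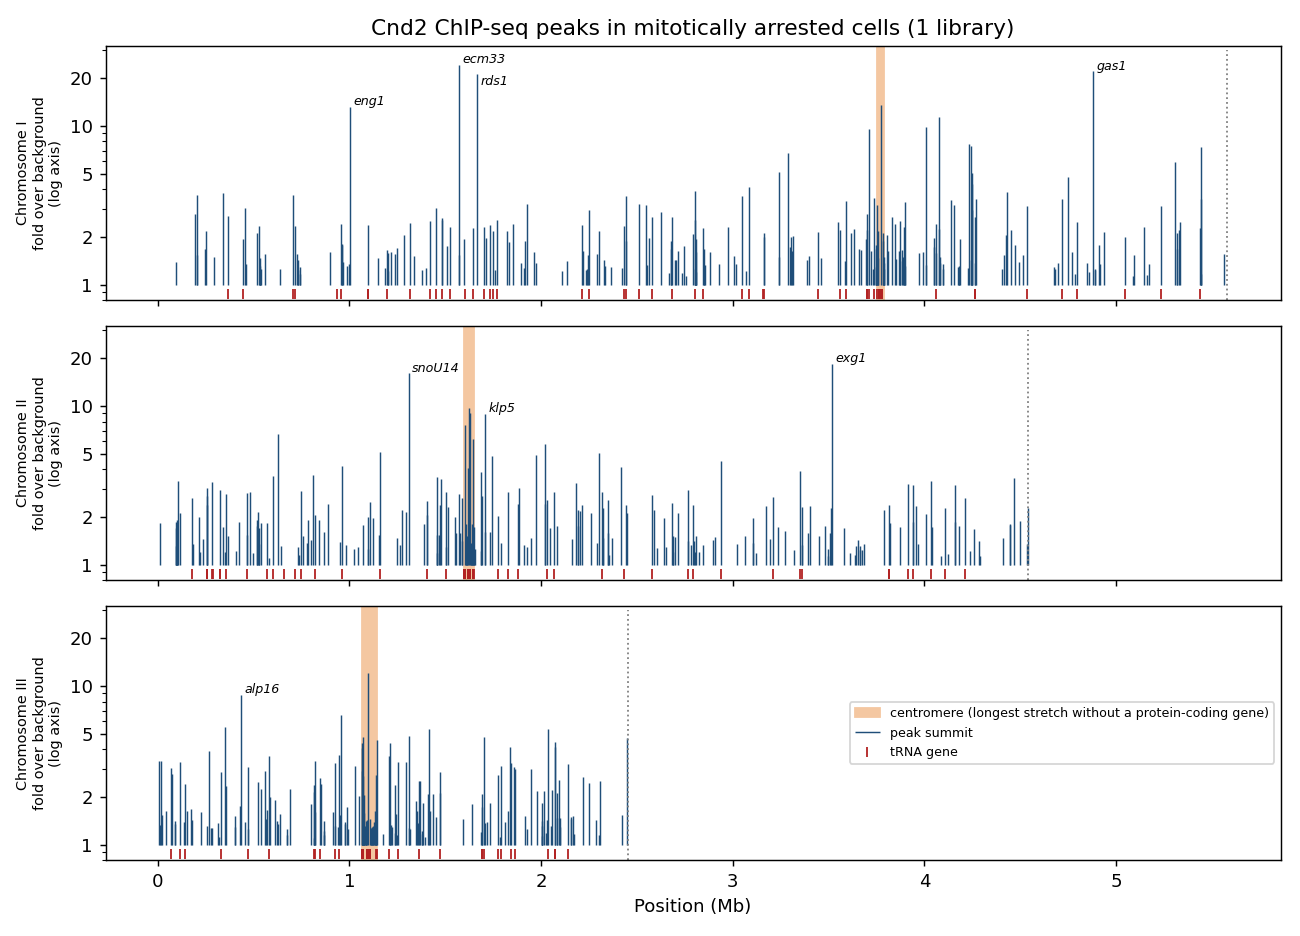
Fold enrichment over the local background (log axis) of each Cnd2 peak against its position in Mb on chromosomes I, II and III, with tRNA genes as red ticks, centromeres shaded and dotted lines at the chromosome ends. The highest peak reached 24.4-fold beside ecm33 on chromosome I, and tall peaks stood in all 3 centromeres.

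The strongest peak (chromosome I, 1568609 to 1571230) covered SPAC1705.02 and most of the convergent gene ecm33, with its summit 184 bp past the 3′ end of ecm33, a cell wall protein gene, and 20 bp inside the 3′ end of SPAC1705.02. The next (I, 4877198 to 4880217; 22.1-fold) had its summit in the short gene cmc4, 242 bp past the 3′ end of gas1, which encodes a glucanosyltransferase of the cell wall. A 21.3-fold peak (I, 1666972 to 1669043) had its summit inside rds1, 1842 bp before its 3′ end. This summit was 89 and 131 bp from the 3′ ends of SPAC343.21 and SPAC343.20, which encode uncharacterized proteins. The peak at exg1, a cell wall glucosidase gene, reached 18.5-fold (II, 3515008 to 3517482), 143 bp past the coding gene and inside the non-coding RNAs SPNCRNA.6162 and SPNCRNA.6163. A peak at snoU14, a small nucleolar RNA gene, reached 16.1-fold (II, 1307907 to 1309822). Next outside the centromeres came eng1, whose glucanase digests the septum at cell separation, at 13.3-fold (I, 999233 to 1003847), and adg2 at 11.5-fold (I, 4077497 to 4080534), where the summit lay inside SPNCRNA.3820.

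Other genes on the arms among the 20 strongest peaks were klp5, alp16 and cdc22. The peak at klp5, a kinesin-8 motor gene, had 8.93-fold enrichment, with its summit inside klp5 and 159 bp from the 3′ end of gua1. That at alp16, a gamma-tubulin complex gene, had 8.76-fold, with its summit inside alp16 and SPNCRNA.6848 and 118 bp from the 3′ end of SPCC306.11. That at cdc22, the large subunit of ribonucleotide reductase, had 7.70-fold. The rest on the arms were the non-coding RNA gene prl53 at 9.93-fold, the valine tRNA gene SPATRNAVAL.04 at 9.62-fold, dal2 (allantoicase) at 7.48-fold, SPNCRNA.271 at 7.35-fold and rpc82, a subunit of RNA polymerase III, at 6.75-fold. At cdc22 the summit lay 208 bp past the gene, within SPNCRNA.3891 and SPNCRNA.3893. Of the 20, 5 lay in centromeres, and 11 of the other 15 had a summit within 500 bp of the 3′ end of a protein-coding gene.

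**Figure D2:**
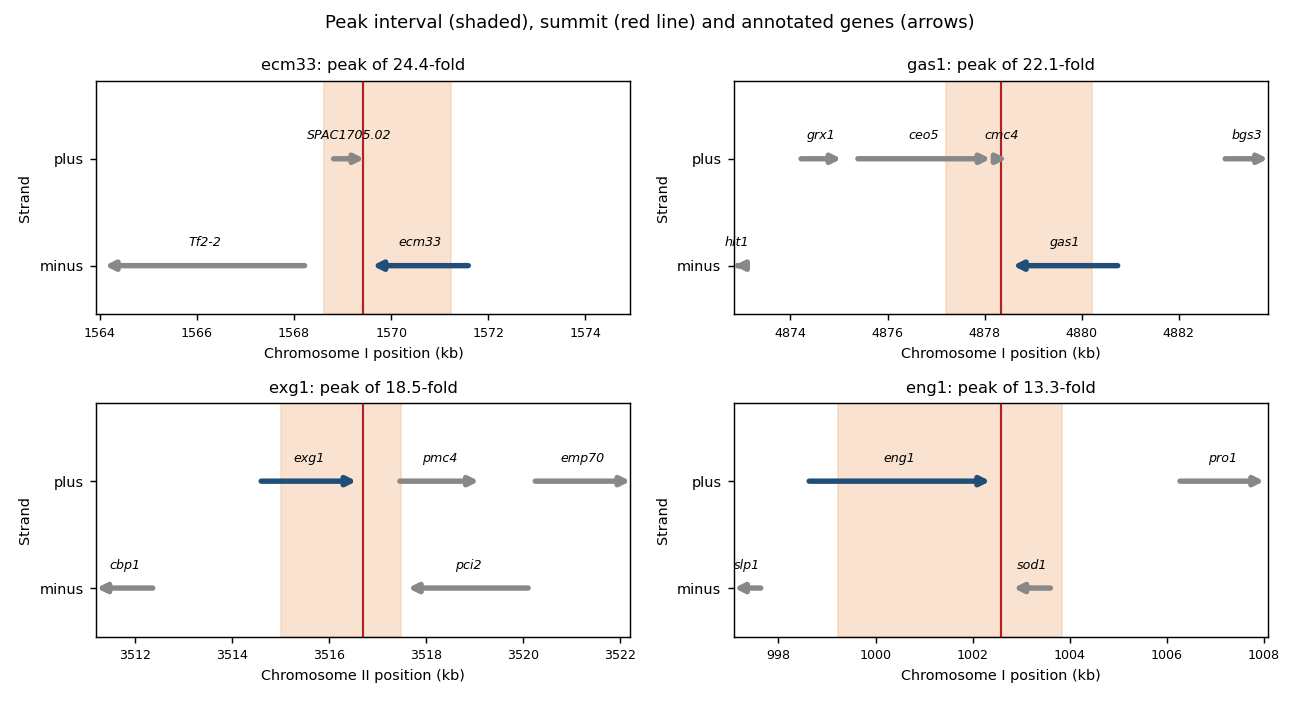
Peak intervals (shaded) and summits (red lines) at ecm33, gas1, exg1 and eng1, with annotated genes as arrows on the plus and minus strands against position in kb. Each summit lay past the 3′ end of the named gene, by 184, 242, 143 and 223 bp.

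Genes read by RNA polymerase III, which makes tRNAs, 5S ribosomal RNA and a few other small RNAs, had Cnd2 peaks far more often than randomly placed peaks did. A summit lay inside or within 500 bp of 127 of 171 tRNA genes (74.3%, exact 95% interval 67.0 to 80.6), against a mean of 9.86 and a range of 4 to 18 over 10000 random placements. The same was found at 28 of 36 5S rRNA genes (77.8%, 60.8 to 89.9), against 2.19 at random. All 3 of the other listed genes of this class were near a summit, against a random range of 0 to 1. These were srp7, the signal recognition particle RNA, at 3.49-fold, snu6 (U6) at 1.96-fold, and rrk1, the RNase P RNA, at 1.72-fold.

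Outside the centromeres, 110 of 116 tRNA genes (94.8%, 89.1 to 98.1) were near a summit. Inside them the count was 17 of 55 (30.9%, 19.1 to 44.8), but peak intervals overlapped all 55, as wide peaks with 1 summit each spanned several tRNA genes. The 116 peaks near a tRNA gene had their summit a median of 39.5 bp from the middle of the gene. Peaks near tRNA genes were also stronger than random sets of peaks from the list, with a median of 2.86-fold against 1.57 to 1.94. The highest were at the centromeric leucine gene SPCTRNALEU.12 (12.04-fold), at SPATRNAVAL.04, and at the neighbours SPBTRNAILE.07 and SPBTRNAALA.10, which shared a 9.05-fold peak in centromere II. The 5S genes had a median of 2.34-fold (random range 1.46 to 2.22), with SPRRNA.06 at 4.78-fold, SPRRNA.26 at 3.28-fold and SPRRNA.11 at 3.05-fold. The first and second of these peaks had their summit upstream of the 5S gene and were also near the tRNA genes SPCTRNAASN.06 and SPCTRNAARG.09, and the 22 peaks near a 5S gene but no tRNA gene had a median of 2.27-fold. The median of all 28 fell within the random range when pileup height replaced fold (892.5, range 647 to 989.5). With summits inside the gene required, fewer peaks were used. Their median of 2.28-fold lay within a random range that was wider, at 1.41 to 2.34.

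Among genes read by RNA polymerase II, those of mitosis and cell separation, of the G1/S transition, of the cell wall, of glycolysis and of protein synthesis had more peaks than random placement gave. A summit was near 15 of 25 mitotic and M/G1 genes (60%, 38.7 to 78.9) against 4.46 at random, led by eng1, adg2 and klp5. Of the G1/S genes, which the MBF transcription factor controls, 9 of 16 were near a summit against 2.65, led by cdc22, by tos4 at 3.21-fold and by the replication licensing gene cdt1 at 2.87-fold. Of the cell wall genes, 10 of 19 were near a summit against 3.75, led by ecm33, gas1 and exg1.

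Housekeeping genes were also near summits more often than random placement gave. A summit was near 10 of 18 glycolysis and fermentation genes against 2.32 at random, with pgk1 (phosphoglycerate kinase) at 3.19-fold, fba1 (aldolase) at 2.70-fold and pyk1 (pyruvate kinase) at 2.42-fold. For elongation and initiation factors the count was 8 of 11 against 1.73, and tef103 and tef101, copies of the EF-1 alpha gene, stood at 6.64-fold and 3.93-fold, with tif51 (eIF5A) at 3.41-fold. Ribosomal protein genes were near a summit in 61 of 141 cases (43.3%, 35.0 to 51.9) against 12.4, with rpl2302 at 4.83-fold, rpl801 at 4.30-fold and rps2402 at 3.28-fold. The rpl2302 peak ended before the gene, with its summit 473 bp upstream. These 6 lists also lay above random lists of protein-coding genes matched on length. The snoRNA genes, which guide the modification and processing of ribosomal RNA, were near a summit in 26 of 66 cases against 3.81, led by snoU14, by sno52 at 3.79-fold and by snoR69b at 3.18-fold. Spliceosomal snRNA genes were near a summit in 5 of 6 cases against 0.331, with snu6, snu2 (1.80-fold) and snu5 (1.72-fold) the highest.

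**Figure D3:**
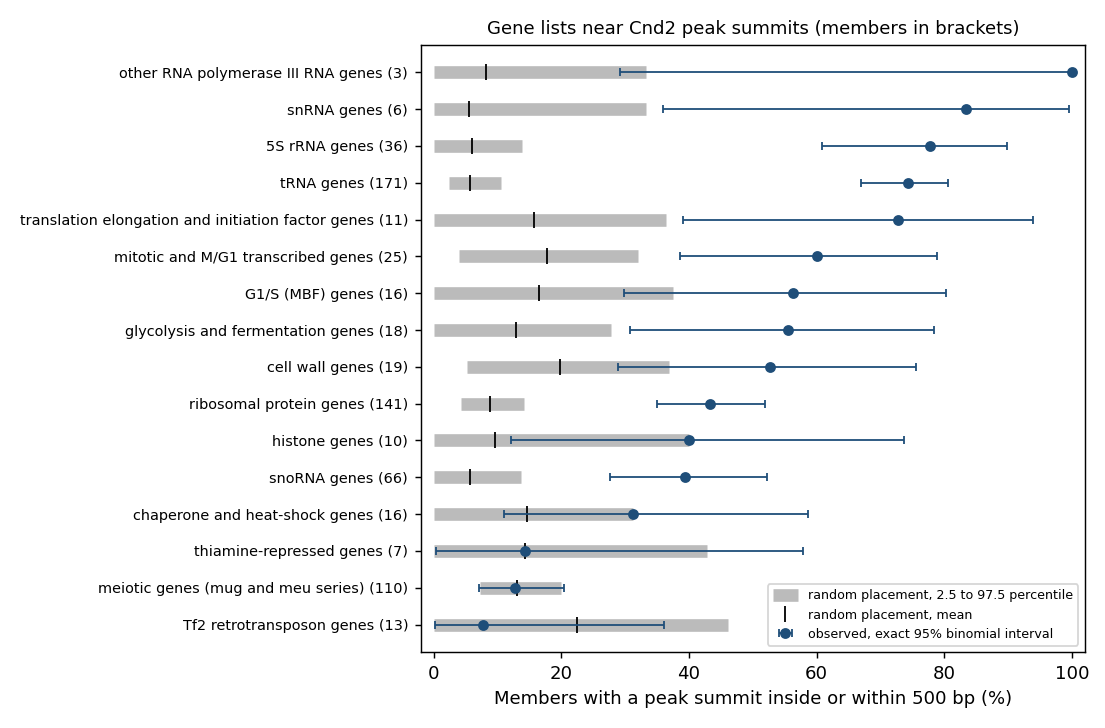
Share of the members of each gene list with a peak summit inside or within 500 bp (points, exact 95% binomial intervals), beside the mean and the central 95% range of 10000 random placements. Of 16 lists, 11 lay above the range, 5 within it and 0 below it.

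For 5 other groups the number near a summit lay within the range of random placement. Genes of meiosis (mug and meu series) were near a summit in 14 of 110 cases (12.7%, 7.14 to 20.4) against 14.4 at random, and the highest folds, at mug62 (3.70), mug70 (3.61) and mug135 (3.35), came from summits upstream of the gene that were also near the tRNA genes SPATRNAVAL.02, SPATRNASER.02 and SPCTRNAGLY.10. Of 13 Tf2 retrotransposon genes 1, Tf2-3, was near a summit (1.36-fold) against 2.91. Among 7 thiamine-repressed genes the only one was thi9, a thiamine transporter gene, against 0.999, and its 2.64-fold peak was also near the tRNA gene SPATRNAMET.02. Chaperone genes were near a summit in 5 of 16 cases against 2.34 (random range 0 to 5), with sks2 at 2.47-fold, ssa2 at 2.21-fold and hsp9 at 1.68-fold. Histone genes stood at 4 of 10 against 0.967 (random range 0 to 4), with htb1 (H2B) at 5.38-fold, hta1 (H2A) at 2.09-fold and hhf1 (H4) at 1.37-fold.

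The lists share members and neighbours share peaks, so the counts are not independent, and repeated sequences such as tRNA, 5S and Tf2 copies are uncertain where the aligner could not place fragments uniquely. When a summit inside the annotated gene was required, the G1/S, cell wall, translation factor, ribosomal protein and snRNA lists and the 3 other RNA polymerase III genes fell within the random range, the glycolysis list did so among peaks at or above the median fold, and the histone list rose above its range under 3 other settings.

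Cnd2 summits lay around the 3′ ends of protein-coding genes more often, and in gene bodies and at 5′ ends less often, than random placement gave. A 3′ end was within 500 bp of 63.1% of summits (419 of 664, exact 95% interval 59.3 to 66.8), against 32.6% at random (29.1 to 36.3). For 5′ ends it was 20.6% (17.6 to 23.9) against 36.3%. Summits with only a 3′ end in reach made up 49.5% against 18.3%, and those with only a 5′ end 7.08% against 22.0%. Gene bodies held 44.4% of summits against 76.3% at random.

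Gaps between convergent genes, bounded by 3′ ends on both sides, held 14.5% of summits (11.9 to 17.4) against 2.41% at random, a ratio of 5.995. Gaps between tandem genes held 28.9% against 10.8%. The centromeres are such gaps by their flanking genes, centromere III a convergent one with 29 summits and centromeres I and II tandem ones with 10 and 14. With centromeres and the last 50 kb left out, convergent gaps held 67 summits against 8.41 at random (ratio 7.97) and tandem gaps 163 against 60.002 (ratio 2.72). Divergent gaps, bounded by 5′ ends, held 11.1% against 10.02%, within the random range. This last share depended on tRNA and 5S rRNA genes: without the 138 peaks near them it lay below its range, at a ratio of 0.569. Among the 332 peaks at or above the median fold the divergent share lay above its range, at 1.80. This filter kept a summit near 126 of the 127 tRNA genes and near all 28 5S rRNA genes that had one. It thus raised the part of the list that lies near these genes, on which the divergent share depended. The rise was not tested without them.

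**Figure D4:**
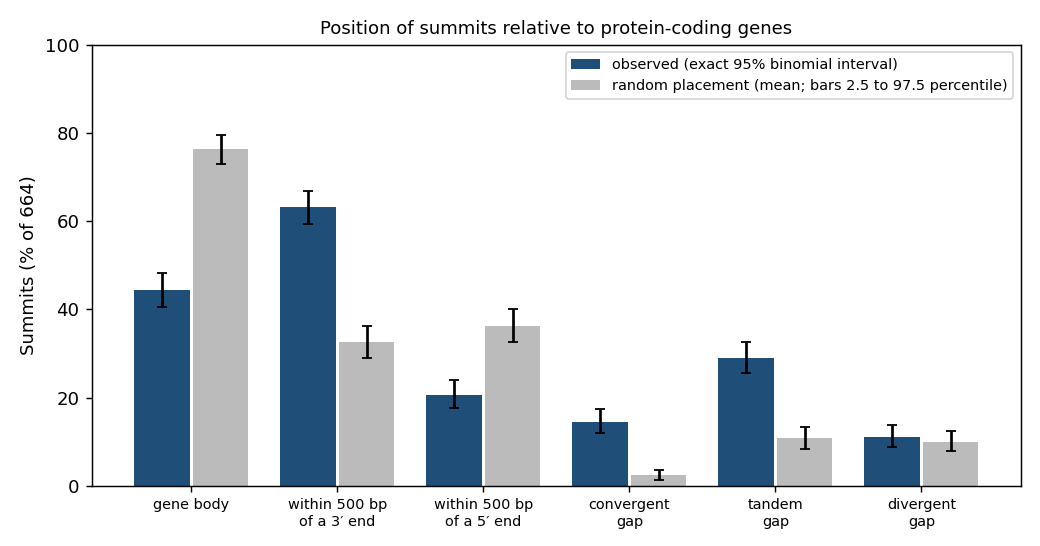
Share of the 664 summits (%) in protein-coding gene bodies, within 500 bp of 3′ and 5′ ends and in 3 kinds of gap between genes (blue, exact 95% binomial intervals), beside the mean of 10000 random placements (grey, bars over the central 95% range). Summits within 500 bp of a 3′ end made up 63.1% against 32.6% at random.

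Centromeres held more Cnd2 summits than random placement gave, a few of them in very wide peaks. The number near chromosome ends lay within the random range when ribosomal DNA peaks were counted. Taken as the longest stretch of each chromosome without a protein-coding gene, the centromeres held 53 summits against 10.1 at random (range 4 to 17). Peaks covered 79.1% of centromere I (I, 3751730 to 3790923), 76.6% of centromere II (II, 1596745 to 1648231) and 47.0% of centromere III (III, 1064444 to 1142615). In centromere I the main peak was 17325 bp wide with a 13.5-fold summit nearest the non-coding RNA SPNCRNA.233, and in centromere III it was 17438 bp wide and 12.04-fold at SPCTRNALEU.12. In centromere II a peak 12794 bp wide had a 9.79-fold summit nearest SPNCRNA.370, and SPBTRNAASP.05, whose annotated product is an asparagine tRNA, stood at 7.56-fold. The 50 kb at each chromosome end together held 12 summits against 16.8 at random, within the range of 9 to 25. By chromosome there were 1 on I, 4 on II and 7 on III. Most of those on III were ribosomal DNA peaks, with summits at 6369, 13007, 17239, 23874 and 2447937. Without them the total is under 9, the low end of the range, though the range was not recomputed for the remaining peaks. Over 100 kb there were 24 against 33.8, near the low end of the range of 23 to 45.

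The ribosomal DNA repeats at the ends of chromosome III lay under wide peaks too. The peak at the right end (III, 2439592 to 2452848) had a pileup of 79162 fragments over a background of 16866, a fold of 4.69, with its summit 740 bp past the 3′ end of the 28S rRNA gene. In the left array the summits of the 2 widest peaks stood at 3.38-fold and 3.37-fold inside the 28S genes, 312 bp before their 3′ ends. The reference holds few copies of this long array and of the centromere repeats, so these heights are sums over copies and their positions are uncertain.

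Chromosome III carried more Cnd2 peaks per length than chromosomes I and II together (ratio 1.55, exact binomial 95% interval 1.30 to 1.84), and peaks lay closer together than random placement gave. There were 73.8 peaks per Mb on chromosome III (181 peaks, exact Poisson 95% interval 63.4 to 85.4), 50.4 on II (229 peaks, 44.1 to 57.4) and 45.5 on I (254 peaks, 40.1 to 51.5). Outside centromeres and the last 50 kb the densities were 63.7 (53.8 to 75.005), 48.1 (41.8 to 55.03) and 44.7 (39.2 to 50.7) per Mb, so that the intervals of III and II overlapped, and the ratio of III to I and II together was 1.38 (1.14 to 1.67). The background at arm summits was also higher on chromosome III, with a median of 540 scaled fragments against 372 on II and 365 on I, while the median fold there was 1.64 against 1.76 and 1.73. Neighbouring summits were a median of 11.0 kb apart, against 12.8 kb at random (11.8 to 13.8), and among peaks at or above the median fold this spacing was within its random range. The intervals cover counting error only.

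**Figure D5:**
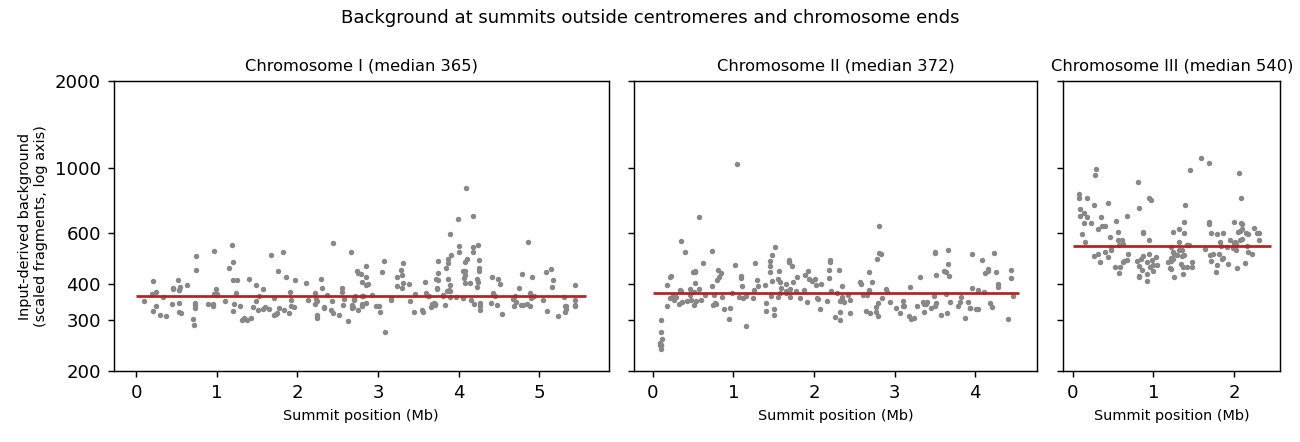
Background at each peak summit outside centromeres and chromosome ends, in scaled fragments (log axis), against position in Mb on chromosomes I, II and III, with each chromosome's median as a red line. The medians were 365, 372 and 540.

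Base composition at the summits was close to that of random positions over 200 bp, with 35.8% GC against 36.1% (range 35.6 to 36.5). Over 500 bp it was lower, at 33.9% against 36.1% (range 35.7 to 36.4). Peaks at the listed genes other than tRNA and 5S rRNA genes had median folds within the range of random peak sets, for example 2.18 at cell wall genes (1.38 to 2.40) and 1.63 at ribosomal protein genes (1.53 to 2.06).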

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

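Outside the 3 chromosomes, peaks were called on a separate sequence named MTR, which no comparison used. It carried 4 peaks, at 5182 to 5586 (1.21-fold), 8451 to 8916 (1.47-fold), 13952 to 15579 (2.11-fold) and 19491 to 20010 (1.88-fold), each called against the input like all others. The last peak ends at 20010 bp, past the end of the 19433 bp mitochondrial sequence of the reference, so the sequence is not that one, and what it represents was not given in the sources used here. No explanation, technical or biological, was tested.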

How the results depend on the processing

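The settings with the background held at the genome mean, with peaks near tRNA and 5S rRNA genes left out, and the chromosome densities without centromeres and ends were chosen after the data were seen. Of 230 values under the alternatives, 208 kept their place above, within or below the random range (for chromosome densities, above a ratio of 1), though 9 of these, all within the range, crossed a ratio of 1. The 208 include the gene body and gap shares at 250 bp, which could not change because that distance does not enter them. Ratios to random placement ran from 7.19 to 82.5 for tRNA genes, 7.29 to 59.3 for 5S rRNA genes, 5.00 to 8.57 for snoRNA genes and 2.36 to 4.67 for mitotic and M/G1 genes, above the range each time. Requiring the summit inside the gene, which by construction leaves out summits beside it, brought into the random range the lists of G1/S genes (2.06), cell wall genes (1.01), translation factors (2.55), ribosomal proteins (1.83), snRNAs (25.8, from 1 gene) and the 3 other RNA polymerase III genes (0), and the fold at 5S rRNA genes (1.33). For all other values here the cause was not tested. Histone genes rose above the range with peak intervals (4.37), without centromeres and ends (4.44) and without peaks near tRNA and 5S rRNA genes (5.21), with 4 genes each time. Among peaks at or above the median fold, glycolysis genes (3.30) and spacing (0.943) fell within the range and divergent gaps rose above it (1.80), as they did at −log10 q of at least 10 (1.33). Without peaks near tRNA and 5S rRNA genes, divergent gaps lay below it (0.569). Pileup in place of fold put 5S rRNA peaks within the range (1.14), and the 500 bp window put GC below it (0.940). A further 5 median folds or heights by list moved outside the range. Chromosome III kept a higher density than I and II together, at ratios of 1.35 to 1.78. The q cutoff and the held background favour the chromosome with the higher background by construction. No paired analysis was possible because each group has 1 library. With 1 ChIP library, depth limits how weak a peak could be called, and the spread between cultures is unknown.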

Other observations

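The tests of an unspecific recovery of transcribed chromatin, of the mix of peak classes on chromosome III and of the copy number of chromosome III were chosen after the results were seen. So were the genes first named in the next paragraph.

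Outside the centromeres and the last 50 kb of the chromosomes, 314 Cnd2 peaks lay near no gene of the lists considered here. The meiotic, Tf2 and thiamine-repressed lists were not considered, so peaks near their genes can be among the 314. Of these 71 exceeded 2-fold, and 71.0% (exact 95% interval 65.7 to 76.0) had a protein-coding 3′ end within 500 bp, against 32.7% at random. Examples were a 5.52-fold peak 211 bp from the 3′ end of pil1, a lipid-binding protein gene (III, 349197 to 352082), and a 4.92-fold peak inside knh4, 460 bp from its 3′ end (II, 1971496 to 1973245). A 5.07-fold peak inside sad1, a spindle pole body gene (II, 2304015 to 2305971), lay 1073 bp from the nearest coding 3′ end. The strongest peaks of this group were among the 20 strongest given above: at rds1 (21.3-fold), prl53 (9.93-fold), alp16 (8.76-fold), dal2 (7.48-fold) and SPNCRNA.271 (7.35-fold). Strong peaks of this group lay on both sides of the 500 bp limit. For example, a 6.75-fold peak was 180 bp and a 6.55-fold peak 1724 bp from the nearest. Long terminal repeats of retrotransposons were near a summit in 15 of 238 cases, against 17.1 at random.

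The excess of peaks at 11 gene lists was set against 2 technical explanations. Weak calls from the low background that the header's genome size allows are argued against, since with the background held at the genome mean 11 of the 11 lists still lay above the random range. Unspecific recovery of transcribed chromatin, which tagged and untagged cells share, may contribute and cannot be told apart from condensin at transcribed genes. Both predict a ratio above the random range at ribosomal protein genes, where it was 4.91, and no untagged control was analysed here.

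For the position of summits near 3′ ends, tRNA and 5S rRNA genes in the gaps could have carried the pattern. Without the peaks near them, the share of summits with only a 3′ end in reach stayed above the random range, at a ratio of 2.84. Unspecific recovery stays open here too, and no biological explanation was tested.

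The background at arm summits of chromosome III was 1.47 times that of I and II (bootstrap 95% interval 1.41 to 1.54). A different mix of peak classes is argued against by summits near tRNA genes alone, with a ratio of 1.41 (1.34 to 1.49), and base composition by the ratio of 1.43 left after the GC trend was removed. All 5 segments of 500 kb on chromosome III had a median background (485 to 650) above all 20 segments of I and II (336 to 417), as more copies of the whole chromosome in part of the cells would give. The segments reuse the summits behind the ratio of 1.47, and any cause along the whole chromosome would give the same. They therefore cannot single out copy number. The medians on III were also uneven, with the highest in the segment at the left end. A higher copy number is a hypothesis for which input coverage along the whole chromosome, not analysed here, would be the next check. The value comes from 1 library, and sequencing the input of another culture could show whether it recurs. Whether higher coverage let weaker peaks pass there stays open. The density of III relative to I and II was 1.55 (1.30 to 1.84) for all peaks and 1.35 (1.04 to 1.74) at or above the median fold. It was 1.63 (1.34 to 1.98) at −log10 q of at least 10 and 1.78 (1.49 to 2.12) with the background held at the genome mean. These last settings cannot decide, since both favour chromosome III by construction. A q cutoff passes weaker folds where coverage is higher. The genome mean of 429 lies above every segment median of I and II and below every one of III.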
